A study of Triticum aestivum with 12 samples.

How the data were processed

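Leaf RNA of 12 wheat plants was measured on the Affymetrix GeneChip Wheat Genome Array, with 1 array per plant. Plants were grown hydroponically with or without silicon, and part of each set was inoculated with the powdery mildew fungus Blumeria graminis f. sp. tritici (Bgt). Silicon feeding at 1.7 mM started 1 week after sowing and inoculation took place 4 weeks after sowing, per the labels' protocols. Plants were harvested and ground one by one, per the labels' protocols, so the 3 replicates of each of the 4 groups were separate plants. The time between inoculation and harvest was not given in the sources used here.

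The deposited values are log2 expression values per probe set, made by RMA (background correction, quantile normalisation and summary over probes), and limma was also used, per the submitters' processing notes. Their versions are not given in the sources used here. The values lay between 2.19 and 14.98, with array medians from 5.34 to 5.43. They were used as deposited. The table held 61290 probe sets, of which 61115 wheat probe sets were tested. The 111 AFFX controls and 64 RPTR controls were left out of the tests, and 25 of the AFFX controls, which read wheat transcripts, were looked at separately. Arrays carry no read depth, and their number limits the precision.

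Gene names came from the platform annotation supplied with the data. It paired 1273 probe sets with 1 gene and none with several, and 59842 wheat probe sets stayed unnamed here. Of its 771 genes, 770 were found in the wheat reference table (assembly IWGSC CS RefSeq v2.1), which was used for names alone. An informative name was left for 200 probe sets of 102 genes. No genome coordinates were used. Probe sets ending in _x, _s or _a_at (12704) can read more than 1 related transcript.

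All 12 arrays were fitted together in limma 3.58.1 (R 4.3.3) with a mean per group, so that the comparisons shared 1 estimate of spread with 8 residual degrees of freedom. The contrasts were mildew without silicon, mildew with silicon, silicon in uninoculated plants, silicon in inoculated plants and the interaction. Benjamini-Hochberg adjustment ran over the 61115 probe sets of each contrast, and an adjusted p under 0.05 was called. The contrast of silicon plus mildew against untreated plants was added after the group structure had been seen. An overall mildew effect was fitted as 6 inoculated against 6 uninoculated plants without regard to silicon. The mean signed deviation over the probe sets it called gave a mildew score per plant, tested by exact exchange of silicon labels within inoculation status (400 exchanges, two-sided).

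The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. By that rule, the text names called probe sets with an informative name and no overlap between the groups (up to 10 higher and 10 lower, 1 per gene), the 3 probe sets with the largest change per comparison, the 5 interactions with the smallest p, and members of the lists. Of 46 keyword lists, 11 matched at least 1 probe set and 1 matched at least 5. Their patterns were matched to gene symbols and synonyms and not to gene titles, so an empty list does not mean that its genes were not measured. Because so few lists matched, 15 lists were drawn up from gene symbols after the annotation was seen and before any gene was tested. Of these, 13 had at least 5 probe sets. Lists of that size were tested with camera at a preset correlation of 0.01, and again with an estimated correlation.

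The limma step was tested on simulated data for mildew without silicon, over 61115 probe sets with the real means and spreads. It recovered 20.9% of 67 probe sets changed by 0.50 log2 units, 86.6% of 67 changed by 1.00 and 97.0% of 66 changed by 2.00. There were 9 false calls among all other probe sets, which were left unchanged. The score test was also simulated, 50 times per setting, with an interaction of -0.5 and a plant SD of 0.1. The exchange of labels called 14 of 50 simulated interactions without a silicon effect and 0 of 50 with a silicon effect of -0.5. A permutation of the residuals of the fit without interaction, which allows for a silicon effect, called 49 of 50 in both settings, and it was added after this weakness and the planned p had been seen. Data without an interaction were simulated 100 times, as the means of the fit without interaction plus the residuals of the 4-group fit, which hold no interaction, permuted as whole arrays. The median residual SD was 0.163 there and 0.158 in the data.

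No pair of arrays looked like 1 hybridisation deposited under 2 labels: the smallest median absolute difference between any 2 arrays was 0.13 log2 units and the largest was 0.27. Alternatives covered a second quantile normalisation, median centring, removal of the dimmest 40% of probe sets, plain _at probe sets alone, the replicate number as a block, other variance models, array weights, fits of the compared arrays alone, stricter thresholds and each array left out in turn.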

Results

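Leaf transcripts were compared among 4 groups of 3 wheat plants: untreated plants (Si-B-), plants inoculated with powdery mildew (Si-B+), plants fed silicon (Si+B-) and plants given both (Si+B+). The cultivar was AC Drummond, which is susceptible to the fungus. The comparisons ask how leaves respond to mildew, how they respond to silicon, and whether silicon changes the response to mildew. The first principal component held 58.2% of the variance. Its scores were 74.9 to 128 in the Si-B+ plants, -28.8 to -4.37 in the Si-B- plants, -41.5 to 7.77 in the Si+B+ plants and -83.3 to -64.6 in the Si+B- plants. Arrays of Si+B+ plants had a median correlation of 0.987 with those of untreated plants and of 0.960 with those of Si-B+ plants.

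**Figure D1:**
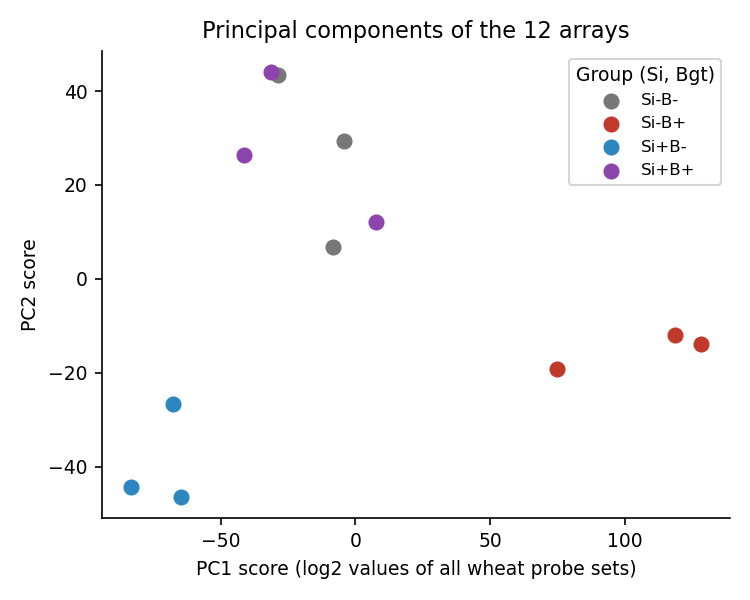
Scores of the 12 arrays on the first and second principal components of the log2 values, with 1 point per plant coloured by group. The 3 Si-B+ plants lie from 74.9 to 128 on the first component and the other 9 plants lie from -83.3 to 7.77.

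Without silicon, mildew raised COMT1, a caffeic acid O-methyltransferase of lignin synthesis, by 0.76 ± 0.15 log2 units (SE, n = 3 per group, limma adjusted p = 0.0059). SAHH, which hydrolyses S-adenosylhomocysteine in the methyl cycle, rose by 0.71 ± 0.13 (limma adjusted p = 0.0034), Hmgb3, an HMG-box chromatin protein, by 0.82 ± 0.11, and the beta-tubulin gene tubb3 by 0.76 ± 0.12. PCS1, a phytochelatin synthase, fell by 0.99 ± 0.15, and lgul, a lactoylglutathione lyase, fell by 1.22 ± 0.33 and fell by 0.93 ± 0.22 on its 2 called probe sets. GSTZ1, a zeta-class glutathione transferase, fell by 0.62 ± 0.12 on 1 of 3 probe sets, and the others did not pass (-0.14 and -0.33). PIMT, which repairs isoaspartate in proteins, fell by 0.84 ± 0.13. Prx1 fell by 0.84 ± 0.25 on 1 of 4 probe sets, and the others did not pass (-0.67, -0.52 and -0.04). RPL9, LTP3, PFK, 1 of 2 probe sets of the histone wcH2A-3 and 1 rbcL probe set fell by 0.68 to 1.01. The pathogenesis-related gene PR5 was 13.70 ± 0.15 (SD, n = 3) in Si-B+ plants and 12.21 ± 0.95 in untreated plants, a difference that did not pass (1.49 ± 0.99 SE, limma adjusted p = 0.37).

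In all, 9985 of 61115 probe sets (16.3%) passed in that comparison, 3591 higher and 6394 lower, and 2341 of them changed at least 2-fold, with the balance turned round (1536 higher and 805 lower). Of the 200 probe sets with an informative name, 6 rose and 20 fell. The largest changes were in unnamed probe sets: TaAffx.54100.1.S1_at went from 5.91 ± 0.41 to 12.02 ± 0.97 (SD, n = 3), Ta.26715.1.A1_at from 3.21 ± 0.24 to 8.68 ± 1.66 and TaAffx.55398.1.S1_at from 5.95 ± 0.66 to 10.99 ± 1.51. The count was 6005 without Si-B- replicate 2 and 6630 without Si-B- replicate 3.

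With silicon, mildew raised WZF1, a zinc finger gene, by 1.08 ± 0.24 log2 units (SE, n = 3 per group, limma adjusted p = 0.029), Hmgb3 by 0.91 ± 0.11 and tubb3 by 0.68 ± 0.12. The histone gene wcH2B-8 fell by 1.54 ± 0.28 (limma adjusted p = 0.013) on the probe set with the largest called change, and 3 of its 7 probe sets passed. The catalase gene CAT1 fell by 0.81 ± 0.19 on a probe set of low level (6.53 in untreated plants), and its abundant probe set (13.90) did not pass (-0.09 ± 0.08). FBP, fructose-1,6-bisphosphatase of the Calvin cycle, fell by 0.44 ± 0.11 on a dim probe set (4.47), and its abundant one (11.24) did not pass (0.20 ± 0.17). The lipid transfer protein gene LTP3 fell by 0.79 ± 0.20 and the avenin-like gene avnla fell by 0.46 ± 0.11, each on 1 of 2 probe sets. The avnla probe set (3.66 in Si+B- and 3.20 in Si+B+ plants) lay under 3.95, the lower quartile of all values. COMT1 and SAHH differed by 0.36 ± 0.15 and 0.26 ± 0.13, which did not pass. In all, 2781 probe sets passed, 1663 higher and 1118 lower, 678 of them by at least 2-fold (449 higher and 229 lower). Among the named ones 4 rose and 7 fell. The unnamed Ta.28631.1.S1_at fell by 5.82 ± 0.30, and Ta.15544.1.S1_at and Ta.26752.1.A1_at rose by 5.64 ± 1.18 and 5.55 ± 1.16. These 2 rose from means under 3.95 (2.56 and 3.88), and their Si+B+ plants spread widely (SD 2.98 and 3.06). The count was 1102, 1016, 1014 and 1535 without Si+B- replicate 1, Si+B- replicate 2, Si+B+ replicate 1 and Si+B+ replicate 3.

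In uninoculated plants, silicon raised some histone genes: wcH2A-9 by up to 2.69 ± 0.48 log2 units (SE, n = 3 per group, limma adjusted p = 0.011) and wcH2B-8 by up to 2.16 ± 0.54. The probe sets of wcH2A-3 disagreed, with a rise of 1.06 ± 0.25 on 1 and -0.45 ± 0.16 on the other, which did not pass. The histone genes wcH2B-6 (-0.08 and -0.23) and wcH2A-2 (0.27) did not pass. The dim FBP probe set rose by 0.51 ± 0.11 and the abundant one did not pass (0.10 ± 0.17). WZF1 fell by 1.74 ± 0.24 (limma adjusted p = 0.0032) and COMT1 by 0.74 ± 0.15. PR5 stood at 8.74 ± 2.59 (SD, n = 3) with silicon and 12.21 ± 0.95 without, and did not pass (-3.47 ± 0.99 SE, limma adjusted p = 0.07). In all, 2656 probe sets passed, 937 higher and 1719 lower, 872 of them by at least 2-fold (194 higher and 678 lower). Of the named probe sets 11 rose and 2 fell. Ta.22591.1.S1_at fell by 5.23 ± 0.54 and TaAffx.28452.1.S1_at by 5.12 ± 0.47, while the largest difference, 5.45 ± 1.66 in Ta.27445.1.S1_at, did not pass. The count was 1144, 1078, 1057 and 1136 without Si-B- replicate 2, Si-B- replicate 3, Si+B- replicate 1 and Si+B- replicate 2.

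In inoculated plants, silicon lowered COMT1 by 1.14 ± 0.15 log2 units (SE, n = 3 per group, limma adjusted p = 0.00061), SAHH by 0.57 ± 0.13 on 1 of 2 probe sets and tubb3 by 0.50 ± 0.12. Profilin-1 and the ribosomal protein gene RPS29 fell on 1 of 2 probe sets each (-0.66 and -0.62). The ubiquitin-conjugating enzyme gene UBC1 fell on 2 of 3 (-0.47 and -0.31) and 1 rbcL probe set fell by 0.37. That rbcL probe set (3.48 in Si-B+ and 3.11 in Si+B+ plants) lay under 3.95, the lower quartile of all values. Abundant rbcL probe sets (14.84 and 14.92 in untreated plants) did not pass (-0.01 each). They lay near the array maxima (14.91 to 14.98), where a change can hardly show, so they do not speak against the called ones. The histone genes wcH2A-9 and wcH2B-8 rose by up to 1.74 ± 0.36 and 1.04 ± 0.28. wcH2A-3 rose by 0.60 on 1 probe set (SE 0.16) and did not pass on the other (0.60, SE 0.25). Hmgb3 rose by 0.36 ± 0.11 on 1 of 2 probe sets. lgul rose by 1.09 ± 0.33 and 0.94 ± 0.22 on 2 probe sets. PIMT, PEAMT1 (phosphoethanolamine methyltransferase), 1 of 3 GSTZ1 probe sets and PFK rose by 0.87 ± 0.13, 0.75 ± 0.14, 0.69 ± 0.12 and 0.63 ± 0.17. Another rbcL probe set rose by 0.56 ± 0.17 and GAPN by 0.44 ± 0.14. In all, 10949 probe sets passed, 6864 higher and 4085 lower, 2340 of them by at least 2-fold, with the balance turned round (547 higher and 1793 lower). Of the named ones 22 rose and 8 fell. TaAffx.108353.1.S1_at and Ta.22668.1.S1_a_at fell by 6.22 ± 0.87 and 6.14 ± 0.60. The count was 6423 without Si+B+ replicate 3. This comparison shares the Si-B+ arrays, with opposite sign, with mildew without silicon. Opposite changes in the 2 are thus favoured by construction and are not separate evidence. Silicon in uninoculated plants shares the Si+B- arrays with mildew with silicon in the same way.

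**Figure D2:**
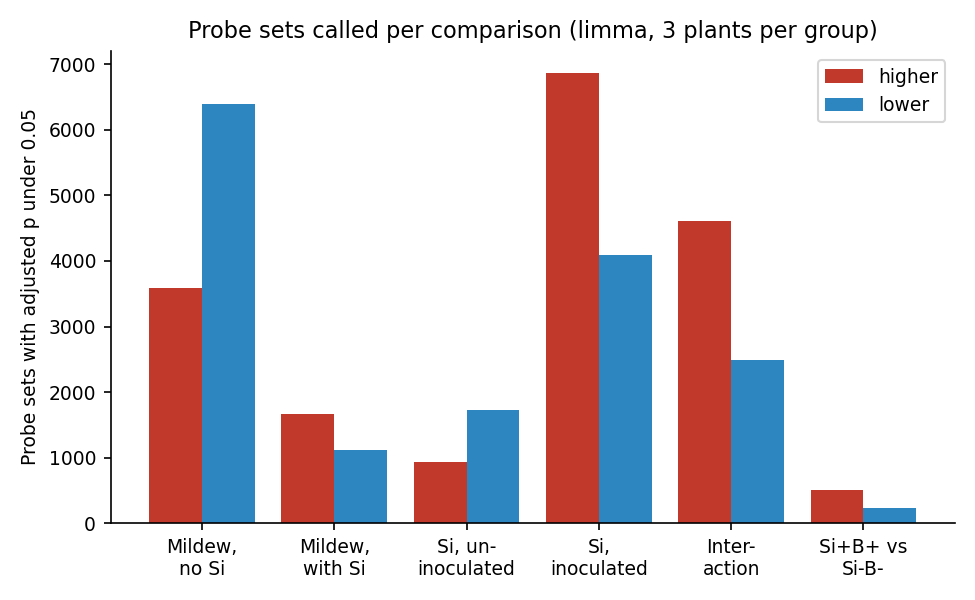
Number of probe sets with a limma adjusted p under 0.05 in each comparison (vertical axis), with higher and lower ones as separate bars. Mildew called 9985 probe sets without silicon and 2781 with it.

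The response of PEAMT1 and of 1 probe set each of GSTZ1 and lgul to mildew differed between plants with and without silicon. This GSTZ1 probe set fell by 0.62 without silicon and differed by 0.18 with it (interaction 0.80 ± 0.17 log2 units, SE, n = 3 per group, limma adjusted p = 0.018). The interaction was 1.15 ± 0.31 on 1 lgul probe set (1.36 ± 0.46 on another, which did not pass) and 0.86 ± 0.19 for PEAMT1. For COMT1 it was -0.40 ± 0.22 and did not pass (limma adjusted p = 0.25). The unnamed TaAffx.108701.1.S1_at was 3.71 ± 0.15 (SD, n = 3) in untreated, 6.71 ± 0.28 in Si-B+, 3.41 ± 0.17 in Si+B- and 3.38 ± 0.16 in Si+B+ plants. The other interactions with the smallest p were -5.06 in Ta.28631.1.S1_at, 1.82 in Ta.28002.1.A1_at, 1.68 in Ta.27957.1.S1_at and -3.09 in TaAffx.107992.1.S1_at. The interaction was called in 7094 probe sets, 4603 higher and 2491 lower, and among the 2183 of at least 2-fold 1081 were higher and 1102 lower. With each array centred on its median, 77.0% of the called interactions were higher, against 64.9% here. The count was 2584, 3386, 3052, 3074 and 2662 without Si-B- replicate 2, Si-B- replicate 3, Si+B- replicate 1, Si+B+ replicate 1 and Si+B+ replicate 3.

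The 3591 probe sets that rose with mildew without silicon had a median change of 0.84 log2 units there and 0.20 with silicon. The 6394 that fell had medians of -0.62 and 0.04. Of the first set 565 were also called higher with silicon and 1385 had a called interaction in the opposite direction, and of the second set 260 and 3387. These probe sets were selected for their change without silicon, and the interaction shares their arrays with opposite sign, which draws the second median toward 0 and the interaction to the opposite side. In 100 simulations without an interaction, added after this result was seen, the median with silicon was 0.78 (0.41 to 1.46) for those called higher and -0.51 (-0.77 to -0.23) for those called lower. The interaction had the opposite sign in 73.5% of the called probe sets there (37.2 to 92.4), against 94.6% here. The simulations called a median of 3114 probe sets for mildew without silicon (725 to 8126), against 9985 in the data. Their called sets therefore differ from the real one in size and selection, and the comparison is rough. Both mildew effects called 934 probe sets, of which 825 went the same way. Independent lists of these sizes would share 97.7 higher and 117 lower probe sets, against 565 and 260 found. The fold changes of both mildew effects, which share no arrays, had r = 0.354 and Spearman's rho = -0.03 across probe sets, which are not independent replicates. Unchanged groups gave r from -0.415 to 0.570 in 100 simulations, so this r lies inside the chance range.

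**Figure D3:**
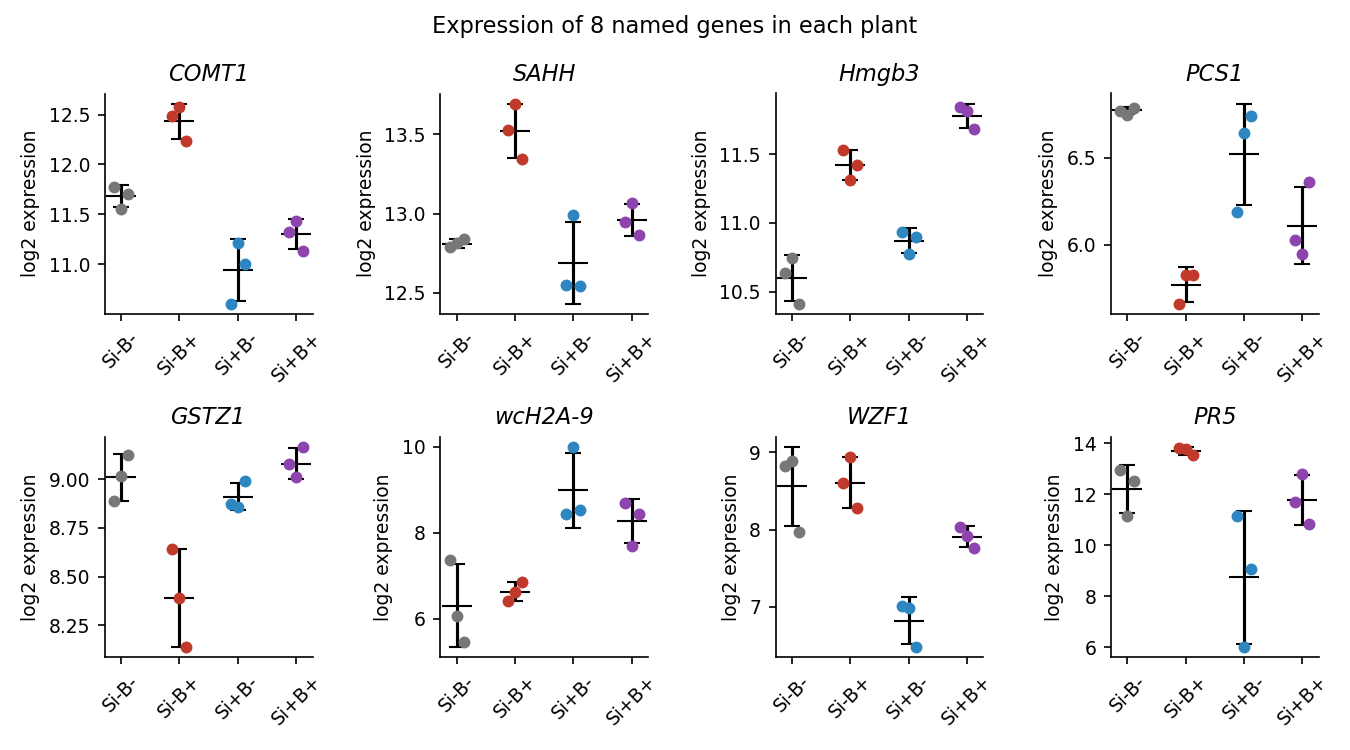
Log2 expression (vertical axis) of 8 named genes in each of the 12 plants, by group, with black marks for the group mean and bars for 1 SD. COMT1 is 12.43 in Si-B+ and 11.30 in Si+B+ plants, and PR5 spreads widely among the Si+B- plants (SD 2.59).

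Without regard to silicon, 690 probe sets passed between the 6 inoculated and 6 uninoculated plants, 361 higher and 329 lower. The mildew score over these was 0.522 ± 0.0936 (SD, n = 3) in Si-B+, 0.360 ± 0.0385 in Si+B+, -0.348 ± 0.0039 in Si-B- and -0.534 ± 0.0635 in Si+B- plants. The inoculated plants lay 0.871 above the uninoculated ones without silicon and 0.894 above with it, a difference of 0.0234 (exact permutation p = 0.855, two-sided, smallest possible 0.005). That p carries little weight, because exchanging silicon labels called 14 of 50 simulated interactions without a silicon effect and 0 of 50 with one of -0.5. Silicon differences in this score were smaller than -0.5 in size, and such a size was not simulated. Permuting residuals gave p = 0.75 (100000 resamples, permutation test). The 690 probe sets were also chosen by a fit in which an interaction counts as noise, so they favour probe sets that respond alike with and without silicon.

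Lists drawn from gene symbols were compared next. Of 18 core histone probe sets of 5 genes, 10 rose with silicon in uninoculated plants (12 higher and 1 lower adjusted over the list alone) with a median of 1.46 (camera adjusted p = 3e-07). In inoculated plants 9 rose (12 adjusted over the list alone, median 0.87, camera adjusted p = 4.7e-05). Neither call held with an estimated correlation (adjusted p = 0.57 and adjusted p = 0.74 with an estimated correlation), nor with 1 probe set per gene. Most of the 10 probe sets that rose in uninoculated plants were of wcH2A-9 and wcH2B-8. With mildew 1 histone probe set fell without silicon and 3 fell with it. Of 14 redox and detoxification probe sets 5 fell with mildew without silicon (6 adjusted over the list alone, median -0.43), and the list did not pass (camera adjusted p = 0.057, adjusted p = 0.80 with an estimated correlation). In inoculated plants 4 of them rose with silicon, in a comparison that shares the Si-B+ arrays with opposite sign. No other symbol list passed camera in the 4 pairwise comparisons.

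Of 6 methyl cycle probe sets 3 rose and 2 fell with mildew without silicon, and 2 rose and 2 fell with silicon in inoculated plants. Of 10 tubulin probe sets 1 (tubb3) rose with mildew in either case. Among 28 rbcL probe sets 3 fell with mildew without silicon and none passed with silicon. The 9 nuclear photosynthesis probe sets gave 0 calls for mildew without silicon and 1 (FBP) lower with it. In the 8 defence-related probe sets 1 (COMT1) rose with mildew without silicon and none with it, and the xylanase inhibitor gene XIP-I did not pass. Mildew without silicon lowered 1 of 22 seed storage and inhibitor probe sets, 2 of 10 translation probe sets and 1 of 10 fructan, starch and sugar probe sets. It changed 0 of 5 purothionin, 0 of 5 serpin and 0 of 10 dehydrin, LEA and Em probe sets. Mean levels of these lists in untreated plants were low (3.56, 3.95 and 4.19), near the lower quartile of all values. A change may not have shown there. The gibberellin 20-oxidases and anther raftins had 4 probe sets each and were not tested as lists. Their mean levels were 5.47 and 4.40 in untreated and 5.28 and 4.25 in Si-B+ plants.

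The keyword lists fixed beforehand were nearly empty. The only one with 5 probe sets was dehydrins, LEA and cold-regulated proteins (camera adjusted p = 0.93 for mildew without silicon). In each comparison 0 of its 5 probe sets were called, also adjusted over the list alone. Within it the 3 Rab15 probe sets differed by 0.12 ± 0.13, -0.16 ± 0.26 and -0.05 ± 0.28 log2 units (SE, n = 3 per group). COR410 differed by 0.02 ± 0.15 and LEA1 by -0.07 ± 0.16. In the smaller lists, the change with mildew without silicon was 0.30 ± 0.13 for 1 of 2 probe sets of the peroxidase PER1. Changes were 0.08 ± 0.12 and -0.03 ± 0.14 for the 2 probe sets of the thionin THI1.3. Those of the serpin WSZ2a and the heat shock gene hsp16.9A were -0.27 ± 0.14 and -0.20 ± 0.53. They were -0.21 ± 0.09 for 1 of 2 probe sets of PsbP of photosystem II, -0.03 ± 0.21 for the starch synthase GBSS-I and 0.14 ± 0.17 for the malate transporter TaALMT1, and none of these passed. The translation factor Eif4B fell by 0.47 ± 0.14 (limma adjusted p = 0.037). In untreated plants COR410 (3.59), LEA1 (3.03), 1 Rab15 probe set (2.88) and THI1.3 (3.10 and 3.03) lay under 3.95, the lower quartile of all values. So did hsp16.9A (3.46) and TaALMT1 (3.86). A change may not show at such levels, so no lack of response can be read from them.

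Plants given both silicon and mildew were also set against untreated plants, a comparison added after the group structure was seen. Hmgb3 rose by 1.18 ± 0.11 log2 units (SE, n = 3 per group, limma adjusted p = 0.00059) and wcH2A-9 by up to 1.79 ± 0.27. Probe sets Ta.26715.1.A1_at, Ta.15544.1.S1_at and Ta.12963.1.S1_at rose by 5.70 ± 1.14, 5.53 ± 1.18 and 5.50 ± 1.13. Their untreated means (3.21, 2.67 and 2.63) lay under 3.95, the lower quartile of all values, so the sizes are rough. The Si+B+ plants spread widely (SD 2.93, 2.98 and 2.98). In all, 740 probe sets passed, 511 higher and 229 lower. Of the 18 core histone probe sets 2 rose (8 adjusted over the list alone, median 0.42). That list passed camera (adjusted p = 2.4e-05) but not with an estimated correlation (camera adjusted p = 0.89). The count was 490, 396, 413, 487 and 251 without Si-B- replicate 1, Si-B- replicate 2, Si-B- replicate 3, Si+B+ replicate 2 and Si+B+ replicate 3.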

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

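The tests of explanations in this part were chosen after the results were seen, except that the alternative scalings of the arrays had been planned as alternatives and were only later used to test an explanation. Groups of 3 plants were too small to look for single outlying plants. The response to mildew differed with silicon in 7094 probe sets by the interaction test. Among named genes the interaction was 0.86 for PEAMT1 and 0.69 for la-17. On 1 probe set each it was 0.80 for GSTZ1, 1.15 for lgul, 1.00 for rbcL, 1.05 for wcH2A-3, -0.89 for CAT1 and -0.57 for FBP. The abundant probe sets of CAT1 and FBP did not pass (-0.04 and 0.40). Nor did 2 abundant rbcL probe sets (-0.02 each), the other wcH2A-3 probe set (-0.46) and the other GSTZ1 probe sets (0.11 and 0.31). The 2 rbcL probe sets lay near the array maxima, where a change can hardly show. It was -3.03 for TaAffx.108701.1.S1_at, -5.06 for Ta.28631.1.S1_at, 1.82 for Ta.28002.1.A1_at, 1.68 for Ta.27957.1.S1_at and -3.09 for TaAffx.107992.1.S1_at.

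Control probe sets outside the main tests also moved. The 3 probe sets for glucose-6-phosphate dehydrogenase (3', 5' and middle), an enzyme of the pentose phosphate pathway, rose with mildew without silicon by 0.66, 1.01 and 0.77 log2 units (limma adjusted p = 0.032 each, over 25 controls). Those for the 5' and middle parts of ubiquitin rose by 0.29 and 0.31. The ubiquitin 3' probe set did not pass (0.09). Silicon in inoculated plants changed the 3 glucose-6-phosphate dehydrogenase probe sets by -0.93, -1.62 and -1.30 (limma adjusted p = 0.0012 to 0.0015). In uninoculated plants it changed the 3' one by -0.71 and 1 of 4 actin probe sets by 0.56 (limma adjusted p = 0.018 and 0.0062). In inoculated plants ubiquitin 5' and middle also changed with silicon (-0.30 and -0.27), as did 1 gapdh probe set (-0.39). That comparison shares the Si-B+ arrays, with opposite sign, with mildew without silicon. Falls in it and rises with mildew are therefore not separate evidence. The interaction was -1.46 for the 5' glucose-6-phosphate dehydrogenase probe set and -0.57 for 1 of 4 actin probe sets (limma adjusted p = 0.041 each). The 3' and middle glucose-6-phosphate dehydrogenase probe sets did not pass (-0.21 and -0.94), nor did the other actin probe sets (-0.19, -0.13 and -0.34).

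Fewer probe sets were called for mildew with silicon than without it, and 4772 of the 9985 called without silicon had a called interaction in the opposite direction. The shared arrays favour that direction. Exchanged labels between the inoculated and uninoculated silicon-fed groups would turn the response round, but 88.3% of the probe sets called in both mildew effects went the same way. This does not exclude an exchange, because probe sets are not independent. The r over all of them (0.354) lay inside the range of unchanged groups (-0.415 to 0.570). Further scaling of the arrays did not remove the called interactions: their count was 5450 after a second quantile normalisation and higher after median centring. The deposited values were already quantile normalised, so these steps cannot show a distortion made by that first normalisation, which is not excluded. Of 100 exchanges of silicon labels within inoculation status, 2 gave as many interactions as the real labels (7094 against 7314 in the highest other), a share under 0.05. That exchange asks whether silicon had any effect, so it speaks against a random division of the plants and does not single out the interaction. The highest other exchanged the labels of all 3 uninoculated pairs, which by construction adds the silicon effects instead of subtracting them. Fewer infection sites or a weaker response per site remain open as biological explanations and were not tested.

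Silicon-fed uninoculated plants stood apart from untreated ones. Weak mildew or stress in the untreated controls may be part of it: 74.9% of the 872 probe sets that silicon changed at least 2-fold moved the other way with mildew (95% binomial interval 71.9 to 77.7, counting error only). This was 61.9% of the higher and 78.6% of the lower probe sets. Of the 1040 probe sets called in both comparisons at any size, 59.8% moved opposite ways. Across all probe sets the 2 effects had r = -0.253 and Spearman's rho = 0.26. The shared untreated arrays push all of these values toward the same direction, so the explanation is left undecided. RNA degradation is argued against, since 0 of 5 control transcripts had 3'-minus-5' differences in the 3 Si+B- arrays above those of the other 9. Silicon itself remains open, and so does any unrecorded difference in harvest or array batch, which cannot be told apart from the group.

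A set of 147 probe sets, none with an informative gene name, lay under 3.95, the lower quartile of all values, on each uninoculated array and rose at least 4-fold with mildew without silicon. Their median was 6.44, 6.87 and 4.98 on the 3 Si-B+ arrays, and 3.27, 3.74 and 3.27 on the 3 Si+B+ arrays. The 147 were selected for a rise on the Si-B+ arrays, which favours lower values with silicon in inoculated plants. In that comparison 143 of them were lower with silicon. The other 4 (Ta.12963.1.S1_at, Ta.13076.1.S1_at, Ta.15544.1.S1_at and Ta.26715.1.A1_at, named after their values were seen) had array medians of 9.60, 7.77 and 6.21 in Si-B+ and 5.18, 10.69 and 9.65 in Si+B+ plants. One source of RNA other than wheat leaf, such as the fungus, read by all of them was not decided by the bounds used. The median silicon change of the 147 was -2.58 and that of the 4 was 0.76, 0.72, 0.63 and 0.23, so 3 of them exceeded it by over 3 log2 units. They fell short of 3 standard errors, and 0 probe sets met both bounds. On Si+B+ replicates 2 and 3, however, the median of the 4 (10.69 and 9.65) stood above its Si-B+ values. The median of the 147 was 3.74 and 3.27 there. On these arrays the 4 did not move in step with most of the set, but they were picked from it by their values. No fungal sequence was used here.

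For the pairwise comparisons, 3 plants against 3 make 10 splits, too few for a share under 0.05. In each of the 5 pairwise comparisons of probe sets, 1 split (the real one) gave as many as the real count: 9985 for mildew without silicon (highest other 1), 2781 for mildew with silicon (0), 2656 for silicon in uninoculated plants (1), 10949 for silicon in inoculated plants (0) and 740 for silicon plus mildew (0). For the overall mildew effect, 1 of 100 drawn splits gave 690 or more (highest other 1), a share under 0.05.

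Splits also tested the symbol lists. With silicon in uninoculated plants 7 of the 10 splits gave as many lists as the real 1 (highest other 2), and in inoculated plants 9 of 10 did (highest other 6). For both mildew effects the real count was 0, which all 10 splits reach by construction, so that count tests nothing. Their highest other counts were 6 without silicon and 3 with it. Camera with the preset correlation thus also called lists in regroupings of the same plants, and the histone list calls rest on little beyond their single probe sets.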

How the results depend on the processing

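The score of the 1000 probe sets with the largest overall change and the permuted residuals were alternatives chosen after seeing the data. Over those 1000 probe sets the inoculated plants lay 2.82 above the uninoculated ones without silicon and 1.43 above with it, a difference of -1.39 ± 0.584 (SE). Its sign is opposite to the planned score (0.0234), with p = 0.385 by exact exchange of labels and p = 0.048 by permutation of residuals. The planned score difference also changed sign, without passing, with a second quantile normalisation (-0.00497) and the trended robust variance (-0.00673), and ranged from -0.0967 to 0.127 with 1 array left out. The score result therefore depends on how its probe sets are chosen and tested, and neither version settles it.

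With a 2-fold minimum the counts were 2341 for mildew without silicon, 678 with silicon, 872 for silicon in uninoculated and 2340 in inoculated plants, 2183 for the interaction and 224 for silicon plus mildew. With adjusted p under 0.01 they were 4968, 688, 690, 5539, 509 and 233. Plain _at probe sets alone, fewer by construction, gave 1776 for mildew with silicon, 380 for the overall effect, 548 for the overlap and 1 list for mildew without silicon. Array weights gave 5840 for silicon in uninoculated plants and 1851 for silicon plus mildew, and the cause was not tested. The histone list calls fell to 0 in both silicon comparisons with an estimated correlation and with 1 probe set per gene.

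Leaving out 1 array, fewer samples by construction, gave 6005 to 9984 for mildew without silicon, 1014 to 3495 with silicon, 1057 to 3224 for silicon in uninoculated and 6423 to 11271 in inoculated plants, 2584 to 8361 for the interaction, 251 to 931 for silicon plus mildew, 327 to 865 for the overall effect and 446 to 1061 for the overlap. The overall effect was 327 and 354 without Si-B+ replicates 1 and 2, 329, 343 and 362 without Si+B- replicates 1, 2 and 3, and 394 without Si+B+ replicate 2. The overlap was 483 and 446 without Si+B- replicates 1 and 2 and 460 and 502 without Si+B+ replicates 1 and 2. Lists called were 0 to 2 and 0 to 1 for mildew without and with silicon and 1 to 2 and 1 to 3 for silicon in uninoculated and inoculated plants.

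The replicate numbers did not pair the plants: deviations of same-numbered arrays correlated from -0.39 to 0.33, and 5 of 12 arrays correlated best with their own number. With the replicate number as a block, mildew with silicon gave 1684 probe sets and the overall effect 303. The other counts stayed within 1.5 times. Alternatives were run for 67 results of single probe sets, the named genes called per comparison and the largest changes, and not for other named genes. None of the 67 changed direction, which their selection largely fixed. The named ones were taken only where the groups did not overlap, so leaving out 1 array could not turn them. Of 804 leave-one-out values 644 stayed on their side of the threshold and 159 lost their call. Of 494 other values 459 stayed and 35 lost it. The most calls lost in 1 setting were 21, without Si+B+ replicate 3, and the replicate block lost 12. The keyword list had under 5 probe sets left, and so no value, without dim probe sets, with plain _at probe sets and with 1 probe set per gene. In simulation 20.9% of changes of 0.50 log2 units were recovered for mildew without silicon. The simulation changed far fewer probe sets than the data called, which makes its adjusted threshold stricter. That share therefore does not carry over to the data, where Eif4B was called at -0.47.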

Other observations

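Some probe sets with large differences between group means did not pass, and their plants spread widely within groups. GLU1A had an interaction of 2.74 log2 units (limma adjusted p = 0.085) and XIP-I differed by 1.26 with mildew without silicon (limma adjusted p = 0.11). The unnamed Ta.27445.1.S1_at was 9.77 ± 4.92 (SD, n = 3) in Si+B- plants and 4.28 to 4.71 in the means of the other groups.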
